A study of Mus musculus with 3 samples.

How the data were processed

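Single-cell RNA was measured in 3 libraries of adult mouse testis cells sorted for bright CD9 and ID4-EGFP, 1 each labelled control, rapamycin and rapamycin release. Each library was pooled from 3 males by the series design, while the protocol speaks of 2 or more mice. The deposited matrices hold raw UMI counts per gene and cell, whole numbers without any normalization. Reads were turned into counts with Cell Ranger 3.1 on mm10/GRCm38, per the submitters' processing notes. Each matrix lists 31054 features, EGFP included, and its number of barcodes equals the number of cells that the labels state (2275, 5253 and 1219). No cell filter is described in the labels, and the lowest totals per barcode were 500, 500 and 507 UMIs. The protocol also describes sedimentation fractions of spermatocytes and spermatids, which were not analysed here.

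Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrial genes. This passed 1158 control, 4458 rapamycin and 476 release cells, and without the mitochondrial limit 1971, 4638 and 1110 would have passed. Doublets were marked with Scrublet in scanpy per library. It marked 6 control and 15 release cells, which were left out, and 0 rapamycin cells, against 41, 12 and 221 doublets expected at 0.8% per 1000 barcodes, so it did not work in the rapamycin library. The 1152, 4458 and 461 cells that remained were scaled to 10000 UMIs and log-transformed. The 2000 most variable genes, scaled to at most 10 standard deviations, gave 30 principal components and 15 neighbours per cell from an exact search, and the Leiden method at resolution 0.8 gave 19 clusters. The 3 libraries were clustered together without a correction for the library. The exact neighbour search replaced an approximate one after the results had been seen, because the approximate one gave different clusters on different processors.

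A cluster took the name of a cell type other than spermatogonia when at least 3 of its markers were found in 25% or more of the cluster's cells and lay at least 1 log2 unit above all other cells (pseudocount 5 CPM), and when they outnumbered the spermatogonial markers that did so. Remaining clusters were named spermatogonia-like when at least 3 stem, undifferentiated, progenitor or differentiating markers lay as far above the clusters already named. A state was given inside the class at a difference of 0.5. A cluster at under 1/3 of the median depth of its libraries with no marker of its class among its leading 10 genes stayed unnamed. Cluster 11, at 0.350 and without such a marker, kept the name spermatid-like. With a limit of 25% or the expected doublets left out the like cluster, at 0.273 and 0.331, had no name. None of the 8 class clusters had more markers of another class than of its own among its leading 10 genes.

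UMI counts were summed over the spermatogonia-like cells of each library and divided by their total to give CPM, UMIs scaled to the same fixed total in each library. Ratios are of CPM with an exact conditional binomial 95% interval, and shares of cells have exact Clopper-Pearson 95% intervals. A gene was tested at 10 CPM or more in the higher library, and counted as higher or lower when its ratio was at least 2 either way and its interval excluded 1. With 1 library per group no test between groups was possible, cells are not replicates, and no p-value was computed. A library with fewer than 3 counts of a gene was set to 3 counts, and the upper limit for a count of 0 also used 3 counts. Summed depth was 11084851 UMIs in 580 control, 49082821 in 3625 rapamycin and 9211594 in 337 release cells of the class.

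Gene lists covered 33 themes: stem cell state, undifferentiated, progenitor and differentiating spermatogonia, pan germ cell, meiotic spermatocyte, spermatid, Sertoli, Leydig, peritubular myoid, macrophage, lymphocyte, endothelial, interstitial mesenchyme, erythroid, mTORC1 pathway, cytosolic ribosomal proteins, translation factors, ribosome biogenesis, glycolysis, nuclear oxidative phosphorylation, mitochondrial genome, sterol and fatty acid synthesis, amino acid response, autophagy and lysosome, S phase, G2 and M phase, cell cycle inhibitors, immediate early and heat shock, p53 response and apoptosis, GDNF and FGF signalling, retinoic acid response, and DNA methylation. For each list with at least 3 members at 10 CPM, the median log2 ratio was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression. A list lay outside its range below percentile 2.5 or above percentile 97.5, and its members were counted as higher or lower at 1.5-fold. Lists share members, such as Gfra1, Ret, Etv5 and Bcl6b in the stem cell state and GDNF lists.

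The genes named per comparison were the 12 with the largest and the 12 with the smallest ratio among genes with at least 50 CPM and a UMI in at least 10% of cells of the higher library, without clone names and mitochondrial genes. To these were added up to 4 members per list with the largest ratio either way, and Id4, Cd9, Gfra1, Etv5, Zbtb16, Neurog3, Kit, Stra8, Mtor, Rps6, Eif4ebp1, Fkbp1a and Ddit4. The filter, the lists, this rule and the alternatives below, other than those named last, were fixed before the data were examined.

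Shares of cells with a UMI were computed for 11 genes after each cell was thinned to 1500 UMIs, which left out 50 control, 121 rapamycin and 7 release cells. The return after release was set beside 200 simulations of counting noise in which the release library kept the rapamycin levels. The alternatives fixed beforehand were no filter, a stricter filter (at least 2000 genes, at most 5% mitochondrial UMIs), marked doublets kept, all cells, median-of-ratios scaling, a total without mitochondrial and ribosomal protein genes, the mean of per-cell CPM, no floor or a floor of 50 CPM, thinned cells, Leiden resolutions of 0.4 and 1.2, and each library clustered alone. A mitochondrial limit of 25%, the expected share of doublets left out, lists within states, in the stem cell state without cluster 8 and in each of its clusters, Leiden seeds 1 to 5, the spermatid-like class without cluster 11, lists set against other genes within 1.2-fold in transcript length (with intervals from resampled members), and the count of genes at 10 times their level in spermatid-like cells were added after the data had been seen.

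The counting steps were tested on data simulated for 31054 genes, with 100 genes at 3-fold and 100 at 1.5-fold. Depths and mean levels were those of all cells that passed the filter in each library, marked doublets included, with counting noise only. Changed genes were drawn from above the 10 CPM floor. The test therefore does not describe the spermatogonia-like class alone or genes near the floor. In rapamycin over control, 100% of the 3-fold genes were recovered, 0% of the 1.5-fold genes were called at the 2-fold limit, and 95% of intervals held the true ratio. In release over rapamycin these were 100%, 0% and 96%, and in release over control 100%, 0% and 94.5%. No other gene was called in any of the 3.

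Coordinates are those of GENCODE M21 on GRCm38, matched by gene identifier for 30934 of the 31054 features. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.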

Results

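The data were 3 single-cell libraries of adult mouse testis cells, made with 10x Genomics droplets after a sort for bright CD9 and a bright ID4-EGFP reporter. CD9 is a surface protein of undifferentiated spermatogonia, and ID4 marks those with stem cell activity, so the sort enriches the stem cell end of the spermatogonial pool. Of the 3 libraries, 1 was labelled control, 1 rapamycin and 1 rapamycin release. Rapamycin binds FKBP12 and inhibits the mTORC1 kinase complex, which couples nutrient and growth factor signals to protein and lipid synthesis. The dose, the length of treatment and the time after release are not given in the labels used here. Each library pooled cells of 3 males by the series design, while the protocol speaks of 2 or more mice, so there was 1 library per group and no replicate of any value.

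The control library held 2275 barcodes and 43165311 UMIs, with a median of 16986 UMIs per barcode. The rapamycin library held 5253 barcodes and 59835590 UMIs (median 11273), and the release library 1219 barcodes and 31814233 UMIs (median 27205). Mitochondrial transcripts took a median of 8.63% of a barcode's UMIs in the control, 5.59% in the rapamycin and 10.6% in the release library. The filter, which includes a limit of 10% mitochondrial UMIs, therefore passed 50.9% of control, 84.9% of rapamycin and 39.0% of release barcodes. All intervals given with values are 95% intervals. Those of gene ratios and of shares of cells cover counting error only. Intervals of list medians come from resampled members, those of ratios of median depth from resampled cells, and those of simulations from the simulated values. None covers differences between animals or libraries.

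**Figure D1:**
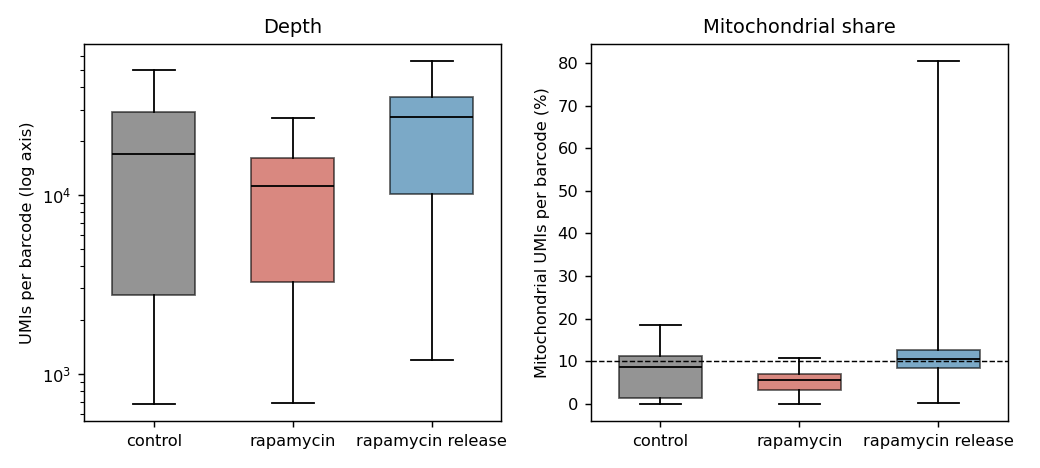
UMIs per barcode (log axis) and mitochondrial share of UMIs (percent) for every barcode of the 3 libraries, as boxes from the lower to the upper quartile with the median as a line, whiskers from percentile 5 to 95, and a dashed line at the 10% limit. Median depth was 16986 UMIs in the control, 11273 in the rapamycin and 27205 in the release library, and the whole filter, on UMIs, genes and mitochondrial share, passed the largest share of barcodes in the rapamycin library (84.9%).

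Germ cells made up most of each library. Spermatogonia-like cells were 50.3% (47.4 to 53.3) of the 1152 control cells, 81.3% (80.1 to 82.4) of the 4458 rapamycin cells and 73.1% (68.8 to 77.1) of the 461 release cells. Spermatid-like cells, in 4 clusters of which 2 had protamine or transition protein genes among their leading genes, were 26.5% (23.9 to 29.1), 9.38% (8.54 to 10.3) and 17.6% (14.2 to 21.4) in the same order. Without cluster 11, which has no spermatid marker among its leading 10 genes, they were 17.3% (15.1 to 19.6), 6.62% (5.90 to 7.39) and 9.33% (6.83 to 12.4). Meiotic spermatocyte-like cells were 9.98% (8.31 to 11.9), 2.15% (1.75 to 2.62) and 3.90% (2.33 to 6.10), and interstitial mesenchyme-like cells 3.91%, 0.942% and 1.08%. Macrophage-like cells were 0.608% of control and 0.359% of rapamycin cells, and none of the 461 release cells, which allows a share of up to 0.651%. Unnamed cells, 298 in 1 shallow cluster, were 8.68%, 4.02% and 4.12%. Effects of the sort and of the depth gap on these shares were not tested. With a limit of 25%, spermatogonia-like cells were 61.9% of control, 66.1% of rapamycin and 83.3% of release cells, since spermatids hold few mitochondrial transcripts and 733 shallow rapamycin cells then fell in a cluster without a name.

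**Figure D2:**
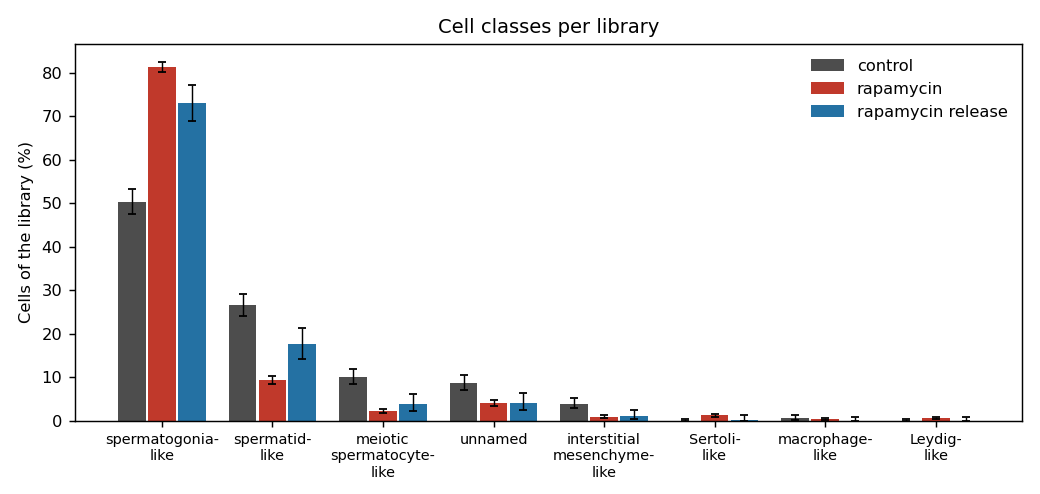
Share of cells (percent, with exact binomial 95% intervals) in each named class for the control, rapamycin and release libraries. Spermatogonia-like cells were 50.3%, 81.3% and 73.1%, and spermatid-like cells 26.5%, 9.38% and 17.6%, under a filter that passed unequal shares of the libraries.

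Comparisons of expression used the 8 spermatogonia-like clusters, with 580 control, 3625 rapamycin and 337 release cells. Clusters 1, 2 and 8 carried markers of the stem cell state, among them Gfra1, the co-receptor for the niche factor GDNF, with Mki67 and replication-dependent histone genes leading cluster 8. Cluster 7 was led by Stra8 and Kit, which mark the retinoic acid-driven entry into differentiation. Clusters 3 and 4 were led by Egr4, Upp1, Ddit4 and Nanos3, the latter a gene of progenitor spermatogonia. Cluster 6, which has no state, had Aspm and Ube2c, the latter of the G2 and M phase list, among its leading genes. It held 7.93% of control, 9.66% of rapamycin and 11.9% of release cells of the class, against 10%, 3.50% and 13.9% for cluster 8. Lists were not taken within cluster 6, so cluster 8 is not the only cluster with a leading gene of that list. The largest cluster of the class differed between libraries: cluster 5, at 0.256 of the depth of other cells of its libraries, was the largest in the control (19.5% of the class), cluster 4 in the rapamycin (19.4%) and cluster 2 in the release library (38.3%). Median depth in the class was 19780, 13057 and 27576 UMIs per cell in the control, rapamycin and release libraries, which is 0.660 for rapamycin over control, 2.11 for release over rapamycin and 1.39 for release over control.

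The first comparison, rapamycin over control, asks which transcripts of spermatogonia differ under inhibition of mTORC1. In the rapamycin library, transcripts of the stem cell state, of sterol synthesis and of mitosis stood lower than in the control library, and ribosomal protein mRNAs and the small RNA Bc1 stood higher. Bc1, a short RNA polymerase III transcript, was at 1923 CPM (UMIs scaled to a fixed total per library) against 216 in the control, a ratio of 8.90 (8.55 to 9.27). Hmgcs1, an enzyme of the mevalonate pathway, was at 43.5 against 96.3 CPM (0.451, 0.419 to 0.486). Mcam, a surface protein of stem cell state spermatogonia, was at 44.2 against 103 CPM (0.427, 0.397 to 0.459). Of 8467 genes tested, 17 were at least 2-fold higher, 75 at least 2-fold lower and 8375 between. The median log2 ratio of all tested genes was −0.25, and gene lists are given with their median log2 ratio and its distance from that value.

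Of the stem cell state list, 0 of 13 members were at least 1.5-fold higher, 7 lower and 6 between. Its median was −0.62, or −0.38 relative to all genes, at percentile 0.01 of matched random lists. Besides Mcam, the lower members included Ret, the GDNF receptor kinase (0.545), Eomes, a T-box factor of stem cell state spermatogonia (0.458), and Epha2 (0.469). Gfra1 was at 56.4 against 83.6 CPM (0.675) and Etv5, a transcription factor induced by GDNF, at 34.8 against 52.0 CPM (0.668). The GDNF and FGF signalling list was at −0.55 (−0.30 relative), with 4 of 14 members lower and 10 between. The clusters of the stem cell state held 995 of 3625 rapamycin and 212 of 580 control cells of the class. Within them alone the stem cell state list stood at −0.0011 and the GDNF and FGF signalling list at 0.0058 relative to all genes, both inside their ranges. Within cluster 8 these lists stood at −0.31 and −0.36, below their ranges. Within the differentiating cluster, with 443 rapamycin and 58 control cells, the stem cell state list stood at −0.84, with 8 of 9 members lower, and the GDNF and FGF signalling list at −0.39. These clusters were named with this same list. The list also differed with the mitochondrial share inside a library: in the control it was 0.41 higher, relative to all genes, in cells under the 10% limit than in cells between 10% and 25%. Id4, which the reporter of the sort follows, was at 66.9 against 114 CPM (0.588, 0.551 to 0.628), EGFP at 17.5 against 41.7 CPM, and Cd9, the other gate of the sort, at a ratio of 1.06 (1.01 to 1.11).

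Among genes of differentiation, Kit, the receptor for stem cell factor, was at 38.3 against 18.3 CPM (2.09, 1.81 to 2.43; 0.557 under the stricter filter, with 21 control cells), and Stra8, a retinoic acid target needed for meiosis, at 154 against 89.9 CPM (1.72, 1.61 to 1.84). The retinoic acid response list was at 0.34 (0.59 relative) with 1 of 6 members higher, 1 lower and 4 between (−0.29 relative under the stricter filter), and included the binding proteins Crabp1 (1.43) and Rbp1 (1.43). The differentiating list was 0.24 above the median of all genes with 2 of 8 members higher, inside its random range. Stra8 depended on the mitochondrial limit, at 1.08 with a limit of 25% and 1.01 without a filter, and Kit was at 1.56 with a limit of 25%. The undifferentiated list (−0.34), in which Zbtb16, a self-renewal factor, was at 0.684, and the progenitor list (−0.12) also lay inside their ranges. Neurog3, a progenitor gene, was at 1.58, and at 0.691 after each cell was thinned to 1500 UMIs. That thinned ratio rests on few cells with a UMI, 1.32% (0.533 to 2.70) of control and 0.913% (0.625 to 1.29) of rapamycin cells, whose intervals overlap.

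Of the sterol and fatty acid synthesis list, 0 of 24 members were higher, 14 lower and 10 between, with a median of −0.65 (−0.40 relative), below all 10000 matched random lists. Idi1, an isomerase of the mevalonate pathway, was at 42.9 against 90.9 CPM (0.472, 0.438 to 0.510), Msmo1, a sterol oxidase, at 0.469 (0.426 to 0.517; 1.19 under the stricter filter), and Ldlr, the receptor that takes up cholesterol, at 5.38 against 15.2 CPM (0.353, 0.290 to 0.431). Scd2, a fatty acid desaturase, was at 0.437. Glycolysis genes were at −0.31 with 6 of 17 lower, among them Pfkp (0.491) and the glucose transporter Slc2a1 (0.512), inside the random range. The amino acid response list was at −0.25 with 1 of 16 lower, Aars, the alanyl-tRNA synthetase (0.443).

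Of the G2 and M phase list, 0 of 49 members were higher, 19 lower and 30 between, with a median of −0.52 (−0.28 relative), below all matched random lists. Lower members were the mitotic kinesins Kif11 (0.541) and Kif23 (0.570), the anaphase activator Cdc20 (0.560) and the condensin subunit Smc4 (0.567). The S phase list was at −0.23 (0.01 relative) with 1 of 41 lower, Rrm1 (0.596). The immediate early and heat shock list was at −0.45 (−0.21 relative) with 6 of 17 lower, including Hspa1a (0.427) and Zfp36 (0.494), but at 0.060 relative with the mean of per-cell CPM and 0.096 under the stricter filter. Cell cycle inhibitors (−0.25, 2 of 10 lower), the p53 response (−0.38, 2 of 9 lower) and DNA methylation genes (−0.24, 0 of 5 beyond 1.5-fold) lay inside their ranges.

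Cytosolic ribosomal protein mRNAs were at 0.36 (0.61 relative), above all matched random lists, with 14 of 81 members higher, 0 lower and 67 between. Rpl37 was at 9697 against 4684 CPM (2.07, 2.05 to 2.09), Rpl36 at 1.92 and Rpl39 at 1.82, while Rps6, the substrate of the mTORC1 target S6 kinase, was at 0.789. Rps27rt (3.42), Wdr89 (3.38), Nme2 (2.63) and Rpl22l1 (1.95) also stood higher, but share sequence with paralogs or retrocopies, so their counts are uncertain. Translation factors were at −0.23 (0.01 relative) with 1 of 32 lower, and at 0.02 under a median-of-ratios scaling. Ribosome biogenesis genes were at −0.24 with 1 of 29 lower. The mTORC1 pathway list was at −0.27 (−0.03 relative) with 5 of 33 members lower, among them Sesn2, a leucine sensor (0.480), and the mTORC1 brakes Tsc2 (0.587) and Tsc1 (0.597). Mtor itself was at 0.802, Ddit4, an mTORC1 inhibitor, at 0.823 (1.05 in thinned cells), Fkbp1a, which encodes FKBP12, at 1.06, and Eif4ebp1, a translation repressor, at 1.07 (0.911 with a limit of 25%). Rptor, the scaffold of mTORC1, was at 0.534, and at 0.880 in thinned cells. Autophagy and lysosome genes were at −0.32 with 4 of 29 lower, among them Gba (0.441) and Ulk1, an mTORC1-controlled kinase that starts autophagy (0.603).

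Nuclear oxidative phosphorylation genes were at 0.03 (0.28 relative), with 6 of 83 lower and 77 between, including Sdhd of complex II (0.529). Against other genes of like transcript length, however, this list was at −0.0096 (−0.057 to 0.045, resampling members), while the sterol list stood at −0.41 (−0.65 to −0.13), the stem cell state list at −0.38 (−0.54 to −0.24) and the G2 and M phase list at −0.23 (−0.30 to −0.17). Against such genes the intervals held both signs for immediate early genes (−0.14, −0.32 to 0.065) and the retinoic acid response (0.49, −0.0087 to 0.88). They also did for the spermatid list (0.38, −0.026 to 0.44) and translation factors (0.044, −0.077 to 0.15). Genes of the mitochondrial genome, whose share the filter limits, were at −0.26 with 1 of 13 higher and 5 lower, among them mt-Nd3 (0.432) and mt-Co3 (0.491). Relative to all genes this list turned from −0.01 to 0.055 with the mean of per-cell CPM, 0.17 in thinned cells, 0.38 with all cells and 0.71 under the stricter filter. Pan germ cell genes were at −0.31 with 2 of 10 lower, including the RNA-binding protein gene Dazl (0.597). Meiotic genes were at 0.07 (0.32 relative) with 2 of 11 higher, including Syce3 of the synaptonemal complex (1.72). The spermatid list was at 0.24 (0.48 relative) with 2 of 13 higher, Prm1 (1.68) and Tnp1 (1.58). Prm1 was at 1834 CPM in control and 3079 CPM in rapamycin spermatogonia-like cells, which is 1.52% and 2.27% of its level in spermatid-like cells of the same libraries (120810 and 135659 CPM), and RNA carried over from other cells was not separated from expression. Among other genes of high level, Ubc, a polyubiquitin gene, was at 256 against 680.4 CPM (0.376, 0.365 to 0.386), the ubiquitin-activating enzyme Uba1 at 0.486, the collagen crosslinker Loxl2 at 28.9 against 81.9 CPM (0.353, 0.325 to 0.384), and Stat3 at 0.497.

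With all cells in place of the class, the stem cell state (0.17), GDNF and FGF signalling (0.19), meiotic (−0.086) and spermatid (−1.37) lists turned direction relative to all genes. The difference between the rapamycin and control libraries has no replicate check, and scaling moved it: a median-of-ratios scaling gave 45 genes higher and 14 lower (76.3% higher, against 18.5%), and a total without mitochondrial and ribosomal protein genes 30 and 43 (41.1%). With a 25% mitochondrial limit 38 genes were lower, 24 of them among the 75, and the stem cell state list stood at −0.17 relative to all genes, GDNF and FGF signalling at −0.14, the G2 and M phase list at −0.12, immediate early genes at −0.07, the retinoic acid response at 0.21, the sterol list at −0.53 and ribosomal proteins at 0.62.

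**Figure D3:**
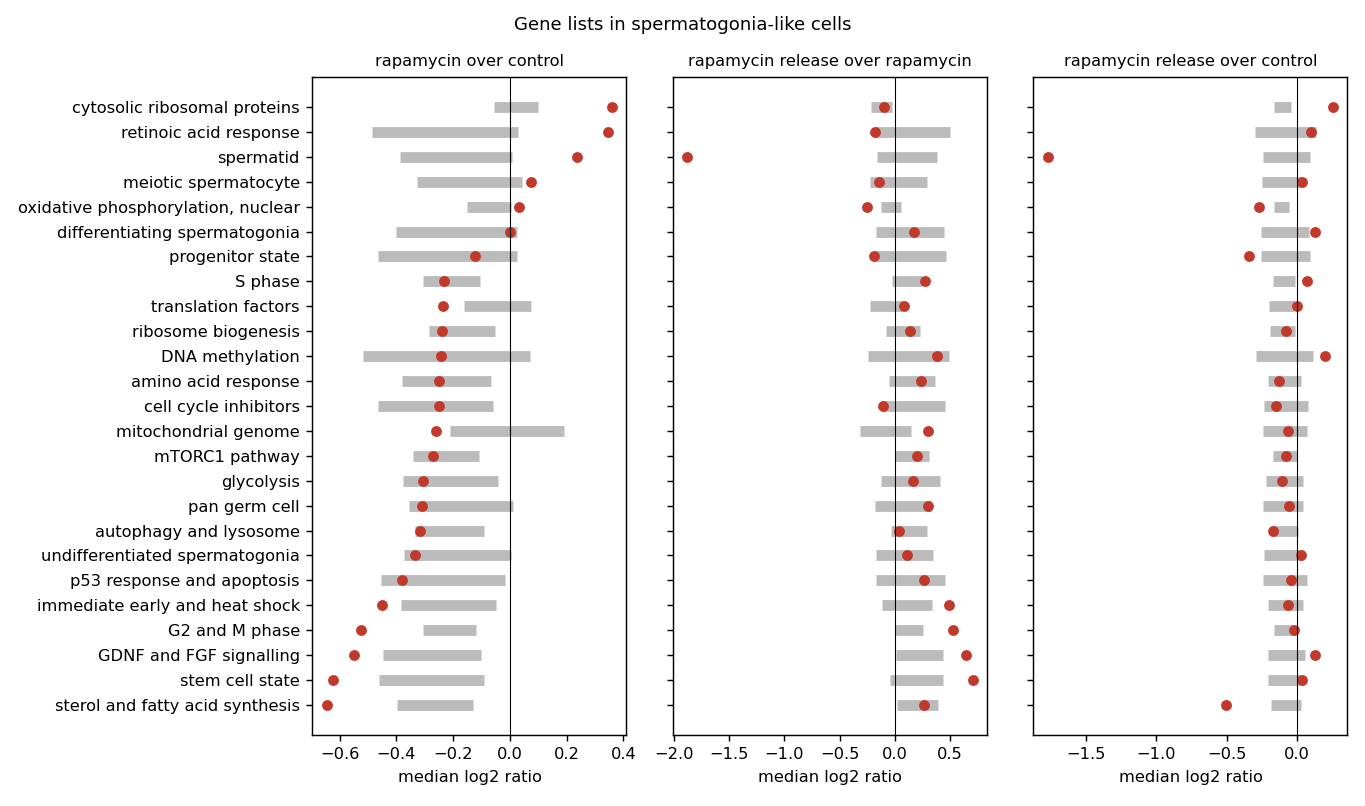
Median log2 ratio of each gene list (red points) in the 3 comparisons of spermatogonia-like cells, with the central 95% of matched random lists as grey bars and a line at a log2 ratio of 0. In rapamycin over control the sterol (−0.65), stem cell state (−0.62) and G2 and M phase (−0.52) lists lay below their bars and ribosomal proteins (0.36) above, and in release over control the sterol list (−0.50) lay below its bar.

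The second comparison, release over rapamycin, asks which transcripts differ once inhibition has been lifted. In the release library, stem cell state, GDNF and FGF signalling and mitotic transcripts stood higher than in the rapamycin library, and Bc1 stood lower. Mcam was at 130.5 against 44.2 CPM (2.96, 2.75 to 3.17) and Mki67, a marker of cycling cells, at 174 against 58.8 CPM (2.95, 2.78 to 3.14). Bc1 was at 239 against 1923 CPM (0.124). Of 8429 genes tested, 76 were at least 2-fold higher, 199 lower and 8154 between, and the median log2 ratio of all genes was 0.18. Of the 199 lower genes, 177 had at least 10 times the level in spermatid-like cells of the rapamycin library that they had in its spermatogonia-like cells, and 22 did not, so most of this count was not separated from RNA carried over from spermatids.

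Of the stem cell state list, 11 of 14 members were higher and 3 between, with a median of 0.70 (0.53 relative), above all matched random lists. Within the stem cell state clusters alone, with 207 of 337 release and 995 of 3625 rapamycin cells of the class, it stood at 0.16 relative with 4 of 15 higher, inside its range. Without cluster 8 it stood at 0.26 with 5 of 16 higher, above its range. It was above its range in cluster 2 (0.25) and inside it in clusters 1 (0.19) and 8 (0.13). Within the differentiating cluster it stood at −0.49 with 33 release cells. The class thus held unlike shares of these clusters in the 2 libraries, and the part of this in the 0.70 was not separated. Epha2 (2.18), Ret (1.89), Etv5 (1.63) and Gfra1 (1.56) were among the higher members in the whole class. So was Id4 (1.57, 1.46 to 1.68), which the sort selects through its reporter. EGFP was at 39.9 against 17.5 CPM and Cd9 at 0.834. The GDNF and FGF signalling list was at 0.65 (0.47 relative) with 11 of 16 higher, including Dusp4, a feedback phosphatase of ERK signalling (2.13), and Bcl6b, a GDNF-induced repressor (1.79). Relative to all genes it stood at 0.24 within stem cell state clusters and −0.15 within the differentiating cluster. Without cluster 8 the GDNF and FGF list stood at 0.29, above its range. It was above its range in cluster 2 (0.36) and inside it in clusters 1 (0.14) and 8 (0.29). Kit was at 0.513 (0.438 to 0.598), and Stra8 at 0.879. The progenitor list was at −0.19 (−0.37 relative) with 2 of 6 lower, Nanos3 (0.608) and Upp1 (0.617), but at 0.0032 relative to all genes with a limit of 25% and 0.0069 without a filter. Against genes of like transcript length its interval held both signs (−0.41, −0.57 to 0.068). Zbtb16 was at 1.44 and Neurog3 at 0.736. The undifferentiated (0.11), differentiating (0.17), pan germ cell (0.30), meiotic (−0.14), retinoic acid response (−0.18) and DNA methylation (0.38) lists lay inside their ranges.

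Of the G2 and M phase list, 20 of 49 members were higher and 29 between (0.53, 0.35 relative), among them Kif11 (1.98) and Kif23 (1.95), and stood at 0.31 (0.16 to 0.36) against genes of like transcript length. Within stem cell state clusters other than cluster 8, which is led by Mki67, the list stood at −0.08 relative, inside its range, and within cluster 8 (0.16) and the differentiating cluster (0.19) above its range. In cluster 1, with 31 release cells, it was at −0.22 with 2 of 47 higher and 6 lower, below its range, and in cluster 2 at −0.02, inside. The S phase list was at 0.27 (0.09 relative, 0.0023 against genes of like length) with 5 of 41 higher, and cell cycle inhibitors at −0.11, inside their range, with 3 of 10 higher. The immediate early and heat shock list was at 0.49 (0.32 relative) with 7 of 16 higher, including the AP-1 genes Fosb (2.90) and Jun (1.76). Translation factors were at 0.08, though −0.10 relative to all genes and under a median-of-ratios scaling, with 5 of 32 higher, including Eef1a1 (1.80), Eif4g1 (1.70) and Eef2 (1.67). The mRNAs of Eef1a1 and Eef2 carry terminal oligopyrimidine tracts, which put their translation under mTORC1 control. Ribosomal protein mRNAs were at −0.10 (−0.28 relative) with 7 of 81 higher, 3 lower and 71 between, inside the random range, but at 0.15 (0.095 to 0.24) against genes of like length; Rps6 was at 1.56, and Rpl13a (2.57) and Rpl12 (2.14) have many pseudogenes, which leaves their counts uncertain.

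The mTORC1 pathway list was at 0.20 (0.03 relative) with 5 of 33 higher, including Rptor (1.82), Tsc1 (1.76) and Tsc2 (1.66), and 1 lower. Mtor was at 1.23 (0.844 in thinned cells), Ddit4 at 0.621, Eif4ebp1 at 0.738 and Fkbp1a at 0.891. The sterol list was at 0.26 (0.08 relative) with 1 of 21 higher and 20 between, inside its range, and Hmgcs1 was at 1.46. Nuclear oxidative phosphorylation genes were at −0.25 (−0.43 relative) with 2 of 83 higher and 6 lower, among them Ndufa3 (0.566), but at 0.0025 (−0.052 to 0.056) against genes of like transcript length. Genes of the mitochondrial genome were at 0.30 with 5 of 13 higher, including mt-Co3 (2.34), and 1 lower, mt-Nd4l (0.313), but the list stood at −0.14 relative to all genes in thinned cells and at −0.12 with the mean of per-cell CPM. Autophagy and lysosome genes were at 0.04 with 2 of 28 higher and 2 lower, the ATG8 family members Gabarapl1 (0.385) and Map1lc3b (0.662). Ribosome biogenesis (0.14), glycolysis (0.17), the amino acid response (0.24) and the p53 response (0.27) lay inside their ranges.

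The spermatid list was at −1.88 (−2.06 relative) with 11 of 12 lower, and at 0.18 relative with all cells. Prm1 was at 453 against 3079 CPM, 6.80-fold lower, Tnp1 at 0.171 and Prm2 at 0.195. These levels were 0.417% and 2.27% of those in spermatid-like cells (108635 and 135659 CPM), and Tnp1 was at 0.478% and 2.47%, so this difference was not separated from RNA carried over from spermatids. Ubc was at 747 against 256 CPM (2.92) and Nefm, a neurofilament gene, at 2.71.

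The difference between the release and rapamycin libraries has no replicate check either, and a median-of-ratios scaling gave 25 genes higher and 257 lower (8.87% higher, against 27.6%). The balance turned the other way in thinned cells, with 443 higher and 251 lower (63.8%), and with all cells, with 90 and 55 (62.1%). Of the thinned counts, 35 higher genes were among the 76 and 144 lower genes among the 199. At 1500 UMIs in each of 330 release cells the 10 CPM floor rests on few UMIs, so counting noise was not separated from the turned balance. With a 25% mitochondrial limit 22 genes were higher, 16 of them among the 76, and the G2 and M phase list stood at 0.21 relative to all genes and the sterol list at 0.25, above its range.

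**Figure D4:**
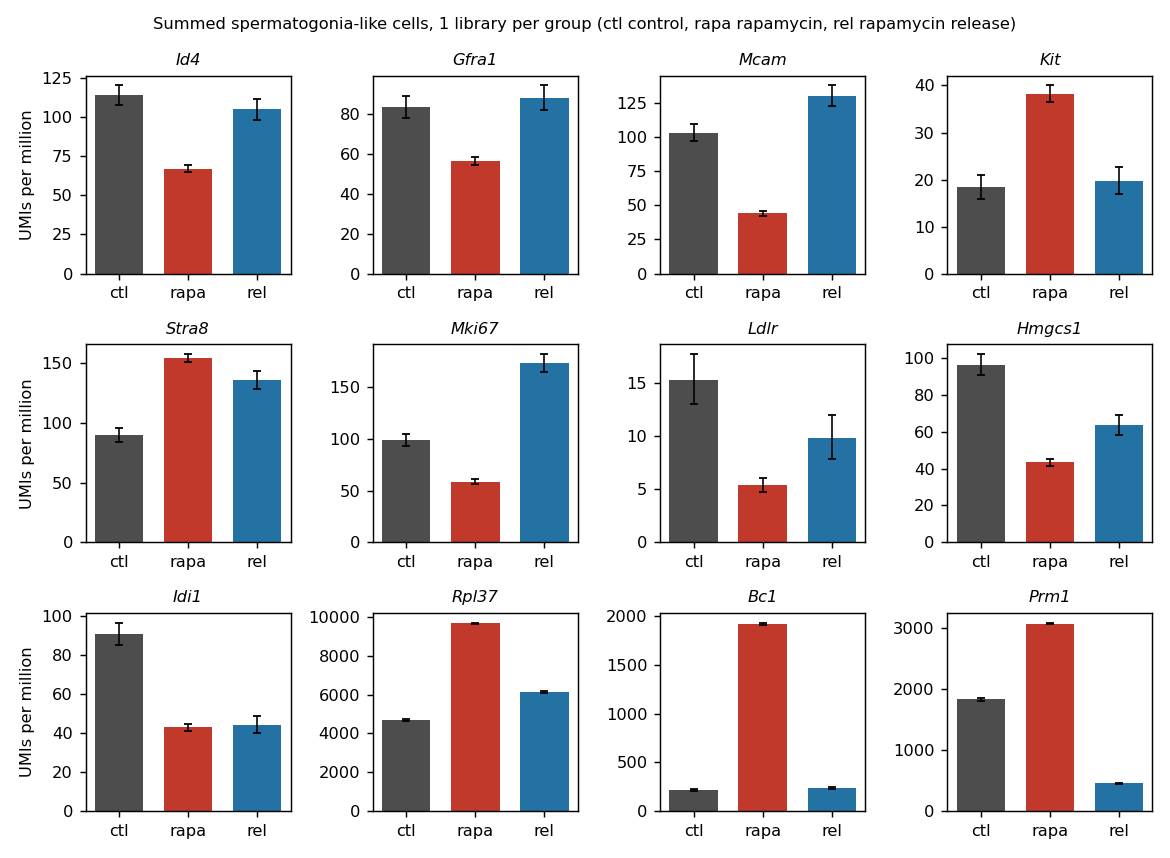
CPM of 12 genes in the summed spermatogonia-like cells of the control (grey), rapamycin (red) and release (blue) libraries, as bars with 95% counting intervals, each gene on its own axis from 0. Bc1 stood at 216, 1923 and 239 CPM in that order, Mcam at 103, 44.2 and 130.5 CPM, and Idi1 at 90.9, 42.9 and 44.3 CPM.

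The third comparison, release over control, asks what still differs after release. Sterol synthesis transcripts were lower than in the control library and ribosomal protein mRNAs higher, and 12 of the 25 lists with a median lay outside their random ranges. Idi1 was at 44.3 against 90.9 CPM (0.487, 0.433 to 0.547), about the level of the rapamycin library (42.9 CPM). Of 8582 genes tested, 10 were at least 2-fold higher, 173 lower and 8399 between, with a median log2 ratio of −0.08. Of the 173 lower genes, 159 had at least 10 times the level in spermatid-like cells of the control library that they had in its spermatogonia-like cells, and 14 did not, so most of this count was not separated from RNA carried over from spermatids.

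Of the sterol list, 0 of 24 members were higher, 10 lower and 14 between, with a median of −0.50 (−0.42 relative), below all matched random lists. Msmo1 (0.562), Mvk, the mevalonate kinase (0.568), and Insig1, the sterol-controlled brake on SREBP (0.565), were among the lower members. Ribosomal proteins were at 0.26 (0.34 relative) with 3 of 81 higher and 78 between; the 3 included Rpl13a (1.87) and Rpl36a (1.57), whose counts pseudogenes leave uncertain. Rps6 was at 1.23. The spermatid list was at −1.77 (−1.69 relative) with 12 of 13 lower, including Hmgb4 (0.268), Tnp1 (0.271) and Tnp2 (0.271), and Prm1 was at 453 against 1834 CPM (0.247). These Prm1 levels were 0.417% and 1.52% of those in spermatid-like cells (108635 and 120810 CPM), and expression was not separated from carried-over RNA. Nuclear oxidative phosphorylation genes were at −0.27 (−0.19 relative), with 83 of 83 between 1.5-fold limits, and at −0.039 (−0.075 to −0.015) against genes of like transcript length. Against such genes the sterol list was at −0.42 (−0.55 to −0.31) and ribosomal proteins at 0.51 (0.45 to 0.54).

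The stem cell state list was at 0.04 (0.12 relative) with 1 of 14 higher, Bcl6b (2.47), inside its random range, and at 0.23 relative to all genes with a limit of 25%. Without the cluster led by Mki67, the list stood at 0.20 relative to all genes within stem cell state clusters, above its range. It was above its range in cluster 2 (0.32) and inside it in cluster 1 (0.18). Within the cluster led by Mki67, with 47 release and 58 control cells, it stood at −0.28, below its range. In the whole class Gfra1 was at 1.06 and Etv5 at 1.09. Id4, under the gate of the sort, was at 0.921 (0.846 to 1.00), and at 1.06 with a limit of 25%, EGFP at 39.9 against 41.7 CPM and Cd9 at 0.882. The GDNF and FGF signalling list was at 0.13 (0.21 relative), above its range, with 1 of 16 higher. The progenitor list was at −0.34 (−0.26 relative; 0.15 with all cells), below its range, with 2 of 6 lower, Nanos3 (0.547) and Upp1 (0.594). The differentiating list was at 0.13 (0.21 relative), above its range, with 1 of 9 higher, Stra8 (1.51, but 0.967 with a limit of 25%), and Kit was at 1.07 (0.7996 with that limit). Against genes of like transcript length the intervals of the progenitor (−0.27, −0.61 to 0.20) and differentiating (0.31, −0.028 to 0.70) lists held both signs.

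Mki67 was at 174 against 99.1 CPM (1.75, 1.62 to 1.89), the 1 higher member of the G2 and M phase list, which was at −0.02, or 0.06 relative to all genes and under a median-of-ratios scaling, and −0.0076 relative with the mean of per-cell CPM, with 48 of 49 between. Within stem cell state clusters other than cluster 8 it stood at −0.32 relative with 20 of 48 lower, within cluster 8 at −0.05 and within the differentiating cluster at 0.22. The S phase list was at 0.07 (0.15 relative) with 41 of 41 between. The mTORC1 pathway list was at −0.08, the same as all genes, with 1 of 34 higher, Eif4b, an initiation factor phosphorylated by S6 kinase (1.62), and 1 lower, Ddit4 (0.511). Mtor was at 0.988 and Fkbp1a at 0.945, both without a direction that held under the scalings, and Eif4ebp1 at 0.791. Translation factors (0.00), meiotic genes (0.04) and DNA methylation genes (0.20) lay above their random ranges with 0 members beyond 1.5-fold, but meiotic genes were at −0.0065 relative to all genes in thinned cells, −0.0021 without a floor and −0.47 with all cells. The interval of DNA methylation genes against genes of like transcript length held both signs (0.14, −0.12 to 0.29). Immediate early genes were at −0.07 with 2 of 17 higher, Jun (1.52) and 1 other. Undifferentiated (0.03), pan germ cell (−0.06), ribosome biogenesis (−0.08), glycolysis (−0.11), mitochondrial genome (−0.07), amino acid response (−0.13), autophagy (−0.17), cell cycle inhibitor (−0.15), p53 response (−0.04) and retinoic acid response (0.10) lists lay inside their ranges. Zbtb16 was at 0.987 and Neurog3 at 1.16, and both crossed 1 under other settings. Markers of Sertoli, Leydig, peritubular myoid, macrophage, lymphocyte, endothelial, mesenchymal and erythroid cells had fewer than 3 members at 10 CPM in spermatogonia-like cells in every comparison, and gave no median.

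The difference between release and control has no replicate check, and 3 genes were higher with a 25% mitochondrial limit, 2 of them among the 10. Under a median-of-ratios scaling 15 genes were higher and 157 lower (8.72% higher, against 5.46%), and with a total without mitochondrial and ribosomal protein genes 29 and 215 (11.9%). In thinned cells, where the floor rests on few UMIs, 109 were higher and 287 lower (27.5%), 1 of them among the 10 and 118 among the 173.

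The return toward control after release was followed over the 92 genes that differed 2-fold between rapamycin and control. In the release library 87 of them (94.6%, 87.8 to 98.2) lay nearer to control than in the rapamycin library, and the median gene had 75.3% of its log2 difference undone. This exact binomial interval counts genes as independent, which genes of the same libraries are not. As the rapamycin library enters both differences, counting noise without any return was simulated 200 times, which gave 55.2% of genes nearer (46.4 to 64.2) and 1.10% undone. The simulation holds counting noise only. A technical shift of the rapamycin library alone would also leave the release library nearer to control, so a return was not separated from it. Medians by transcript length ran from −0.05 (shortest) to −0.36 (longest) in rapamycin over control, and from −0.14 to 0.40 in release over rapamycin. All 17 genes higher in the rapamycin library lay nearer to control (90.5% undone), as did 70 of the 75 lower genes (73.8% undone). The 5 that did not were Pbld1 (24.9 CPM in the release, 26.2 in the rapamycin and 69.7 in the control library), Phkg1, Gm16222, A330032B11Rik and the pseudogene Olfr1369-ps1, named after their values were seen.

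Shares of spermatogonia-like cells with a UMI were taken after thinning each cell to 1500 UMIs, which left 530 control, 3504 rapamycin and 330 release cells. Spermatid-like cells, given for comparison, had median depths of 8133, 5364.5 and 6230 UMIs before thinning, against 19780, 13057 and 27576 in the class. Top2a, a topoisomerase of dividing cells, had a UMI in 23.6% (20.0 to 27.4) of control, 15.3% (14.1 to 16.5) of rapamycin and 29.1% (24.2 to 34.3) of release cells, and in none of the 289, 390 and 74 spermatid-like cells. Mki67 had one in 7.17% (5.12 to 9.71), 5.59% (4.86 to 6.41) and 12.1% (8.80 to 16.1), beside 0.346%, 0.513% and 0% of spermatid-like cells. Id4, a gate gene, had one in 14.0% (11.1 to 17.2), 9.42% (8.47 to 10.4) and 11.5% (8.28 to 15.5), beside 1.38%, 3.08% and 1.35%. Stra8 had one in 8.11% (5.93 to 10.8), 14.0% (12.9 to 15.2) and 10.6% (7.50 to 14.4), beside 0%, 0.513% and 1.35%. Kit had one in 3.21% (1.88 to 5.09), 4.74% (4.06 to 5.49) and 2.42% (1.05 to 4.72), beside 0.692%, 0% and 0%. Gfra1 (9.62%, 8.59% and 10.9%) and Etv5 (6.604%, 5.42% and 7.58%) overlapped within their intervals between control and rapamycin, beside at most 0.346% and 0.256% of spermatid-like cells. Zbtb16 had one in 12.5% (9.76 to 15.6), 9.53% (8.58 to 10.6) and 19.7% (15.5 to 24.4), beside 0%, 0.256% and 0%. No order was read for Sox3 (9.06%, 8.88% and 7.88%), Rarg (1.70%, 1.40% and 0.606%) and Neurog3 (1.32%, 0.913% and 0.606%), whose shares overlapped or went against their CPM.

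Without thinning, Top2a had a UMI in 56.7% of control, 48.2% of rapamycin and 74.5% of release cells, Mki67 in 29.1%, 23.1% and 45.1%, Id4 in 53.1%, 42.5% and 65.9%, and Gfra1 in 49.0%, 42.1% and 66.5%. The unthinned shares were 43.6%, 30.95% and 59.3% for Etv5, 60.7%, 54.0% and 82.2% for Zbtb16, 13.1%, 18.3% and 19.0% for Kit, and 27.6%, 35.1% and 32.0% for Stra8. They were 39.8%, 42.7% and 46.3% for Sox3, 11.9%, 10.3% and 12.2% for Rarg, and 7.93%, 9.02% and 8.31% for Neurog3, and follow the depth of the libraries in part.

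On GRCm38, Bc1 (ENSMUSG00000115783) lies on chromosome 7 from 144914470 to 144914637, and Hmgcs1 (ENSMUSG00000093930) on chromosome 13 from 119690379 to 119708260. Idi1 (ENSMUSG00000058258) lies on chromosome 13 from 8885501 to 8892451, Mcam (ENSMUSG00000032135) on chromosome 9 from 44134469 to 44142727, and Ubc (ENSMUSG00000008348) on chromosome 5 from 125385965 to 125390202. Id4 (ENSMUSG00000021379) lies on chromosome 13 from 48261228 to 48266026, Gfra1 (ENSMUSG00000025089) on chromosome 19 from 58235604 to 58455909, and Kit (ENSMUSG00000005672) on chromosome 5 from 75574916 to 75656722. Stra8 (ENSMUSG00000029848) lies on chromosome 6 from 34920163 to 34939344, Mki67 (ENSMUSG00000031004) on chromosome 7 from 135689784 to 135716361, Rpl37 (ENSMUSG00000041841) on chromosome 15 from 5116645 to 5119140, and Prm1 (ENSMUSG00000022501) on chromosome 16 from 10796326 to 10805839. Bc1 is annotated as a long intergenic non-coding RNA, and the others as protein-coding genes.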

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

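The tests of the mitochondrial limit on sterol and on G2 and M phase transcripts, and values without cluster 11, without cluster 8 or within single clusters, were chosen after the result was seen, and the other tests before. A signal in cells that no comparison of expression used was Sertoli-like cells, led by Clu, Aard, Cst12 and Cst9, at 1.23% (0.931 to 1.60; 55 cells) of the rapamycin library, 0 of 1152 control cells (up to 0.260%) and 1 release cell (0.217%). A signal of the same kind was Leydig-like cells, led by Insl3, Cyp17a1, Fabp3 and Cyp11a1, at 0.606% (0.399 to 0.880; 27 cells) of the rapamycin library and none of the control (up to 0.260%) or release cells (up to 0.651%). These absences depend on the settings: with marked doublets kept the Sertoli-like cluster held 1 control cell, and with a limit of 25% the Sertoli-like and Leydig-like cells formed 1 cluster of 88 cells, 7 of them control, 76 rapamycin and 5 release.

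Cytosolic ribosomal protein mRNAs were higher in the rapamycin than in the control library (median log2 ratio 0.36). Transcript length was not the whole cause, since they stood 0.31 (0.23 to 0.38) above other genes of like length. The median was 0.33 (0.23 to 0.39) after each cell was thinned, so unequal weights of deep and shallow cells were not the cause. Thinning keeps the expected proportions within each cell, so it cannot decide on depth itself. A shift of the whole library may be the cause, but the test in spermatid-like cells cannot decide. Spermatid-like cells of the same libraries, which no longer divide, had a median of 0.55 (0.41 to 0.67) for the same genes. It was 0.64 (0.47 to 0.89) without cluster 11. This could be technical, an effect of treatment on germ cells of every stage, or RNA carried over from spermatogonia-like cells. Carry-over was not separated: Bc1 in spermatid-like cells was at 1.43% of its spermatogonia-like level in the control and 3.87% in the rapamycin library. An effect of rapamycin on ribosomal protein mRNA in spermatogonia stays open as untested biology.

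The rapamycin library had fewer UMIs per spermatogonia-like cell, 0.660 of the control. The limit on the mitochondrial share was not the cause, as the ratio was 0.542 (0.524 to 0.559) with a limit of 25%, where 839 cells, 702 of them rapamycin, that were spermatogonia-like under the 10% limit fell in a shallow cluster without a name. A lower yield of the whole library could not be told apart from lower RNA content, because the ratio in spermatid-like cells differed from that in spermatogonia by −0.000515 with an interval (−0.194 to 0.250) too wide to decide, as was that without cluster 11 (−0.0874, −0.261 to 0.166). Ratios in the other classes were 0.404 (0.334 to 0.509) in meiotic and 0.505 (0.385 to 0.583) in mesenchyme-like cells. Over the libraries median depth also fell as barcodes rose. It was 27205 UMIs at 1219 barcodes (release), 16986 at 2275 (control) and 11273 at 5253 (rapamycin), and depth was not separated from the number of barcodes. Lower RNA content under mTORC1 inhibition is a hypothesis that was not tested.

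Sterol synthesis and G2 and M phase transcripts were lower in the rapamycin library, by −0.40 and −0.28 on the log2 scale relative to all genes. For the sterol list the values argue against the mitochondrial limit (−0.53, −0.70 to −0.32, at 25%). In thinned cells it stood at −0.44 (−0.76 to −0.33), which argues against unequal weights of deep and shallow cells. Thinning keeps the expected proportions within each cell, so depth itself stays open. The values argue against a different mix of states only for the states tested (−0.39, −0.67 to −0.24, in the stem cell state, the nearer to 0 of these). Inside that state the list stood at −0.45 (−0.65 to −0.26) without cluster 8, which is led by Mki67 and differs in share. It stood at −0.22 (−0.55 to −0.14) in cluster 8 and −0.56 (−0.92 to −0.44) in cluster 1. In cluster 2 (−0.37, −0.48 to −0.07) the interval was too wide to decide. Clusters 3, 4, 5 and 6, which have no state, were not tested, so a different mix of these stays open. For the G2 and M phase list the mix of states, the mitochondrial limit and depth each stay open. That list stood at 0.08 (0.00077 to 0.19) in differentiating but −0.52 in stem cell state clusters. There cluster 8 was 58 of 212 control and 127 of 995 rapamycin cells (−0.36 without it and −0.11 within it). The G2 and M phase list stood at −0.12 (−0.21 to −0.07) with a limit of 25%, and at −0.17 (−0.33 to −0.09) after thinning. With Leiden seeds 0 to 5 the thinned G2 and M phase value ranged from −0.27 to −0.17, on both sides of the limit of −0.2 set for this test. Without thinning it ranged only from −0.279 to −0.277 over these seeds. The clusters alone therefore do not give the thinned spread, and the random draw of thinning was not separated from them. A lower output of the SREBP pathway under mTORC1 inhibition is a candidate explanation of the sterol list. It was not tested, and the difference itself rests on 1 library per group.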

How the results depend on the processing

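The 25% mitochondrial limit, the expected share of doublets left out, lists within states, Leiden seeds 1 to 5, the spermatid-like class without cluster 11, the stem cell state without cluster 8 and genes of like transcript length were chosen after seeing the data, and all other alternatives before. No paired analysis was possible because each group had 1 library without shared animals, and no replicate could be left out. The stricter filter left 21 control, 568 rapamycin and 0 release spermatogonia-like cells, so release comparisons have no value under it. Depth limits the genes under 10 CPM, whose counts are low and intervals wide, and leaving out the floor adds these. In thinned cells the 10 CPM floor itself rests on few UMIs. Unless given here, the cause of a moved value was not tested.

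Genes higher in rapamycin over control numbered 17, and under alternatives that moved the count 64 (stricter filter), 90 (all cells), 45 (median of ratios), 30 (total without mitochondrial and ribosomal protein genes), 159 (no floor), 8 (floor of 50 CPM) and 44 (thinned). Lower genes numbered 75, and 41 (no filter), 815 (stricter filter), 1927 (all cells), 14 (median of ratios), 43 (total without those genes), 115 (per-cell mean), 489 (no floor), 14 (floor of 50), 380 (thinned) and 38 (25% limit). In release over rapamycin, 76 were higher, and 27 (no filter), 25 (median of ratios), 133 (per-cell mean), 558 (no floor), 14 (floor of 50), 443 (thinned) and 22 (25% limit). There 199 were lower, and 55 (all cells), 824 (no floor) and 39 (floor of 50). In release over control, 10 were higher, and 3 (no filter), 53 (all cells), 29 (total without those genes), 29 (per-cell mean), 182 (no floor), 1 (floor of 50), 109 (thinned) and 3 (25% limit). There 173 were lower, and 1309 (all cells), 275 (per-cell mean), 731 (no floor), 24 (floor of 50) and 287 (thinned). Lists outside their range numbered 12 in rapamycin over control (7 under the stricter filter) and 12 in release over control (6 in thinned cells).

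The share of genes nearer to control after release, 94.6%, was 86.2% (no filter), 79.7% (median of ratios), 87.3% (no floor), 86.3% (thinned) and 86.2% (25% limit). The median undone, 75.3%, was 60.6% (no filter), 25.7% (all cells), 55.5% (per-cell mean), 65.1% (no floor), 84.5% (floor of 50), 52.96% (thinned) and 61.8% (25% limit). Spermatogonia-like cells of the control, 50.3%, were 54.9% (no filter), 9.05% (stricter), 57.0% (clustered alone) and 61.9% (25% limit). Those of the rapamycin library, 81.3%, were 65.1%, 73.3% and 66.1% (no filter, stricter, 25% limit), and those of the release library, 73.1%, were 0% (stricter) and 83.3% (25% limit).

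A direction was counted as reversed only where the value had been called, as a list outside its range or a gene at 2-fold, and turned sign. These are as follows, with list medians relative to all genes. With no filter, the progenitor list in release over rapamycin was 0.0069, and with a 25% limit 0.0032. Under the stricter filter, rapamycin over control gave 0.71 for the mitochondrial genome, 0.096 for immediate early genes, −0.29 for the retinoic acid response, and ratios of 0.557 for Kit and 1.19 for Msmo1. With all cells, rapamycin over control gave 0.17 for the stem cell state, −0.086 for meiotic, −1.37 for spermatid, 0.38 for mitochondrial genome and 0.19 for GDNF and FGF genes. There release over rapamycin gave 0.18 for the spermatid list and ratios of 1.38 (Crisp2), 1.05 (Fabp9), 1.06 (Fam71e1), 1.41 (Gsg1), 1.47 (Hmgb4), 1.04 (Hspb9), 1.05 (Prm1), 1.27 (Prm2), 1.00 (Prm3), 1.14 (Tnp1) and 1.22 (Tnp2), and release over control 0.15 for progenitor and −0.47 for meiotic genes. With the per-cell mean, the mitochondrial genome was 0.055 in rapamycin over control and −0.12 in release over rapamycin, immediate early genes 0.060 in rapamycin over control, and the G2 and M phase −0.0076 in release over control. Without a floor the meiotic list in release over control was −0.0021, and in thinned cells −0.0065. In thinned cells the mitochondrial genome was 0.17 in rapamycin over control and −0.14 in release over rapamycin.

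Of the other values, 724 list medians kept their range and 101 moved, as did 2922 and 1352 ratios of named genes, and 75 and 57 shares of cells. Among these ratios 174 without a call lay on the other side of 1, such as Neurog3 in rapamycin over control (1.58, and 0.691 in thinned cells, few of which had a UMI of it). With marked doublets kept, the expected doublets left out or the 25% limit, 1 class cluster had more markers of another class than of its own among its leading 10 genes, with 119, 108 and 138 cells led by Odf1 or Defb19. At the 25% limit 894 shallow cells, 733 of them from the rapamycin library, had no name. Leiden seeds 0 to 5 gave 17 to 19 clusters, 579 to 580 control and 3624 to 3626 rapamycin cells in the class, and 74 to 75 lower genes in rapamycin over control. Over these seeds the sterol list ranged from −0.58 to −0.44 in thinned cells and from −0.39 to −0.26 within states, and the G2 and M phase list from −0.27 to −0.17 and from 0.016 to 0.084. In the unthinned class the sterol list ranged from −0.403 to −0.398 and the G2 and M phase list from −0.279 to −0.277. The clusters alone therefore do not give the thinned spread. The neighbour search was exchanged for an exact one after results had been seen. Under the earlier one the thinned G2 and M phase value lay past the limit set against depth, and here it does not. That change was not separated from the random draw of thinning.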

Other observations

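Values by class, state, transcript length and mitochondrial share were computed after the data had been seen. Bc1, the small RNA with the highest ratio in spermatogonia-like cells, stood higher in the rapamycin than in the control library in every class with enough cells. Its ratio was 8.90 in spermatogonia-like, 11.8 (9.96 to 14.0) in meiotic, 24.1 (14.4 to 43.5) in spermatid-like, 27.5 (10.2 to 104) in mesenchyme-like and 57.4 (24.3 to 178) in unnamed cells. Its level was 3.09 CPM in control, 74.4 CPM in rapamycin and 4.74 CPM in release spermatid-like cells, against 216, 1923 and 239 CPM in spermatogonia-like cells. Spermatid-like cells thus held 1.43%, 3.87% and 1.98% of its level in spermatogonia-like cells, and RNA carried over from these was not separated from expression in any other class.

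Sterol synthesis transcripts stood lower in both states that the clusters resolve. Within stem cell state clusters 13 of 23 members were lower in rapamycin over control, and within the differentiating cluster 14 of 25 (−0.62 relative to all genes, 443 rapamycin and 58 control cells). In release over control the list stood at −0.34 relative to all genes within the stem cell state and −0.40 within the differentiating cluster, the latter with 33 release cells. The stem cell state value differed by cluster, at −0.78 in cluster 1 (31 release cells), −0.17 in cluster 2 (129) and −0.24 in cluster 8 (47). Within stem cell state clusters 34 of 48 G2 and M phase members were lower in rapamycin over control, but these pool cluster 8, led by Mki67, with 58 of 212 control and 127 of 995 rapamycin cells. Without it 27 of 48 were lower (−0.36 relative), and within it 10 of 49 (−0.11). The sterol list stood at −0.56 in cluster 1, −0.37 (−0.48 to −0.07) in cluster 2 and −0.22 in cluster 8. Ribosomal proteins stood at 0.70 and 0.47 relative to all genes in the stem cell state and the differentiating cluster. The stem cell state list itself stood at −0.84 relative to all genes within the differentiating cluster, with 8 of 9 members lower.

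Log2 ratios moved with transcript length. From the shortest to the longest of 4 equal groups of genes, ribosomal protein and mitochondrial genes left out, the median was −0.05, −0.24, −0.32 and −0.36 in rapamycin over control, and −0.14, 0.15, 0.30 and 0.40 in release over rapamycin. In release over control it was −0.20, −0.11, −0.05 and 0.02. Tnp1 was at 709.6 CPM in control, 1124 in rapamycin and 192 in release spermatogonia-like cells, and at 38408, 45510 and 40191 CPM in spermatid-like cells. Cells under the 10% mitochondrial limit had a higher stem cell state list than cells between 10% and 25% in the release library too (0.29 relative, 322 and 573 cells), while the rapamycin value (0.13, 2931 and 113 cells) lay inside its random range at percentile 88.9.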
